A study of Streptomyces chattanoogensis with 6 samples.

How the data were processed

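Total RNA from mycelium of Streptomyces chattanoogensis was amplified, labelled with Cy3 and hybridised to custom 1-colour Agilent arrays, per the labels' protocols. The 6 arrays comprised 3 of the whiGch deletion strain LG01 and 3 of the wild-type strain L10, grouped by the genotype given in the labels. Replicates were numbered 1 to 3 within each group in the order of deposition, and these numbers only name the arrays.

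The deposited scanner output gave spot intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal intensity was background-subtracted and detrended within each array by that software, per the file headers, and was not normalised between arrays. The deposited files also gave flags for each spot (well above background, saturated, non-uniform, population outlier) coded as 0 or 1. A deposited table of the whole series held the authors' values on a log2 scale. From the values, all 6 of its columns held the same sorted values, with a median of 5.27, a minimum of 0.951 and a maximum of 18.5, as quantile normalisation gives. Each column correlated best with log2 processed signal of its own array (Pearson's r 0.994 to 0.999 across probes). The software that made this table was not given in the sources used here.

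Each array held 15709 spots, of which 536 were control spots and were left out. The other 15173 spots carried 8173 probes: 8101 for genes and 72 for features named as contigs. Of the genes, 7401 were open reading frames (ORFs) with a number, measured by 1 spot each, and 700 were listed by probe ID only, measured by 11 spots each. Log2 processed signal was taken minus the array's 75th percentile over non-control spots. Spots flagged as non-uniform or population outliers were dropped and the spots of a probe were averaged. A probe with several spots counted as well above background where more than 50% of its spots did. Genes were tested where the probe was well above background on all 3 arrays of at least 1 group, which gave 6524 tested genes (5980 numbered ORFs and 544 probe-ID genes) and left 1577 untested. A probe not well above background on any array of a group has only a bound there. The fold was then given as "at least", comparing the bright group's mean with the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background.

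Deletion and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.20. On simulated data with 6524 genes for this comparison, 50 genes were changed at each size. Recovery was 0% for genes changed by 0.5 on the log2 scale, 48% at 1, 90% at 2 and 96% at 3, and 2.5% of the calls were false. The data gave many more calls, which makes the adjusted p threshold less strict than in the simulation. These shares may thus be too low for the data: of 1849 called genes, only 1078 changed by 2-fold or more.

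The test, the filter, the alternatives for the count of genes and the rule for named genes were fixed before the data were examined. The rule named whiGch, the members of the natamycin cluster and of the WhiG pathway, the 12 largest rises and the 12 largest falls among changed genes with a described product, and members of gene lists on sporulation, aerial hyphae, secondary metabolism, primary metabolism, stress, transport and regulation. If the files gave no product for any gene, it named the 2 changed genes with the largest rise and the 2 with the largest fall by ID whose 3 deletion arrays all lay on 1 side of the 3 wild-type arrays. The files do not pair ORF numbers or probe IDs with gene names or products, so that last part applied. No member of any planned gene list was matched, the gene-list tests were not run, and whiGch itself was not analysed here.

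Everything that uses the order of the ORF numbers was added after the values were seen. The numbers were taken as the order of ORFs in the genome assembly; strand and contig borders were not used here. A run was defined as 10 or more ORFs that changed the same way by 2-fold or more, with at most 1 other tested ORF between any 2 of them, and was compared with 1000 shuffles of the order. Medians over bins of 100 ORF numbers were compared with 10000 shuffles (2-sided). A broad lower region was defined as at least 4 neighbouring bins that were each below the median of all ORFs at an adjusted shuffle p under 0.05. Array medians over a block were compared by a 2-sided exact permutation test, which cannot go below p = 0.1 with 3 arrays against 3.

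The alternatives were normexp background correction (offset 50), quantile normalisation, median centring, the authors' table, no filter or a filter on all 6 arrays, slide as a block, a replicate block on codes shared by titles, limma with trend and robust variance, a minimum log2 change of 1, limma's treat against a fold of 1.5, an adjusted p under 0.01, an unmoderated test per gene, and leaving out each array in turn. The 75th percentile over genes was added after the values were seen. Normexp had been planned on mean signals and was run on median spot and median background signals, the columns the files hold. Scan date was not run apart from slide because both divide the arrays identically, and single probes were not tested because each gene has 1 probe.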

Results

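Transcript levels of Streptomyces chattanoogensis were measured on 6 arrays. This filamentous soil bacterium makes natamycin, a polyene macrolide used against fungi. The arrays comprised 3 of strain LG01, in which the gene whiGch had been deleted, and 3 of the wild-type strain L10. WhiGch is a sigma factor, a subunit that directs RNA polymerase to its promoters, and its counterpart WhiG is needed for spore formation in other streptomycetes. Mycelium in exponential phase was taken from YEME cultures after 48 h at 30 °C and 200 rpm. Nothing in the labels states that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

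The array design covered 8101 genes, and 7401 of them carried an ORF number between 1 and 8117. The 75th percentile of the processed signal was 124, 210 and 235 on the deletion arrays and 115, 129 and 141 on the wild-type arrays. The number of genes well above background was 6658, 7515 and 6204 on the deletion arrays, and 7011, 6230 and 7012 on the wild-type arrays. No spot was saturated, and the spike-in controls gave slopes of 1.02 to 1.06. Deletion replicate 3 had 206 non-uniform spots and 418 population outliers, against 0 to 1 and 166 to 229 on the other arrays, and 90 genes had no value on it, against 0 on the others. Across the tested genes, which are not independent of one another, log2 levels of the wild-type arrays correlated at r = 0.984 to 0.985. The deletion arrays correlated at 0.941 (replicates 1 and 2), 0.934 (1 and 3) and 0.971 (2 and 3), and the correlations between groups lay between 0.811 and 0.868. The median SD between replicates was 0.28 (log2, n = 3) in the deletion strain and 0.15 (n = 3) in the wild type.

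The comparison of the strains asked which transcripts depend on whiGch, in a study concerned with the place of this sigma factor in natamycin production. Levels differed in stretches of neighbouring ORFs as well as in single ORFs elsewhere. In the stretch from ORF 6036 to 6073, 36 of 38 ORFs rose in the deletion strain, with a median log2 fold change of 4.73. This median was 4.42 with dim ORFs at their bounds and 2.15 with normexp. In the stretch from ORF 5138 to 5172, 29 of 32 tested ORFs fell, with a median of -4.59, or -3.13 with normexp. Lower levels extended over ORFs 3701 to 4400, where 215 of 419 tested ORFs fell and 10 rose, and over ORFs 5101 to 5500, where 148 of 289 fell and 31 rose, with the 29 falls of the stretch from 5138 to 5172 among them. These stretches were chosen after the values were seen.

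Over all 6524 tested genes, 1849 changed (limma, Benjamini-Hochberg adjusted p under 0.05): 741 rose and 1108 fell. Of these, 396 rose and 682 fell by 2-fold or more. The other 4675 genes did not pass the test. The deletion and wild-type values did not overlap for 3134 genes, or 48.0% of those tested, where chance gives 10% for a single gene. Genes on an array are not independent of one another, so 48.0% against 10% is no test of a strain effect. The balance of rises and falls depended on the scaling. The 75th percentile left a median log2 fold change of -0.12 over all tested genes, against -0.0046 with median centring, which gave 970 rises and 931 falls. The authors' table gave 966 rises and 961 falls. The count was 1162 without wild-type replicate 2 and 1093 without wild-type replicate 3. Deletion replicate 3 lay alone on a second slide. With slide as a block, which equals the comparison within the first slide, 1443 genes changed.

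The files do not pair the IDs with gene names, so the deleted gene, the natamycin cluster and the sporulation genes were not analysed here, and the labels were not checked against the level of whiGch. The rule for named genes, which ranked fitted log2 fold changes, took 2 ORFs that rose and 2 that fell; their order differed with normexp. L10.orf6042 rose from -5.95 ± 0.32 (SD, n = 3) in the wild type to 1.33 ± 0.36 (SD, n = 3) in the deletion strain, as log2 signal relative to the array's 75th percentile. The fitted log2 fold change of L10.orf6042 was 7.28 (SE 0.24, limma, Benjamini-Hochberg adjusted p = 2.66e-05). It was not well above background on any wild-type array, so its level is given as at least 34.0-fold higher in the deletion strain, a bound that was not itself tested. L10.orf6040 rose from -3.87 ± 1.35 to 3.11 ± 0.24 (SD, n = 3 each), a log2 fold change of 6.98 (SE 0.61, limma adjusted p = 3.07e-04), and was well above background on 2 of 3 wild-type arrays. Without wild-type replicate 2 its log2 fold change was 6.20. L10.orf5145 fell from 1.93 ± 0.11 to -3.42 ± 1.44 (SD, n = 3 each), a log2 fold change of -5.35 (SE 0.64, limma adjusted p = 0.00114); it was well above background on 2 of 3 deletion arrays. Without deletion replicate 1 its log2 fold change was -4.53. L10.orf5153 fell from 3.32 ± 0.13 to -1.79 ± 0.82 (SD, n = 3 each), a log2 fold change of -5.11 (SE 0.38, limma adjusted p = 1.70e-04). With normexp background correction the 4 log2 fold changes were smaller in size, at 2.81, 3.92, -2.93 and -3.93 in the order given.

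**Figure D1:**
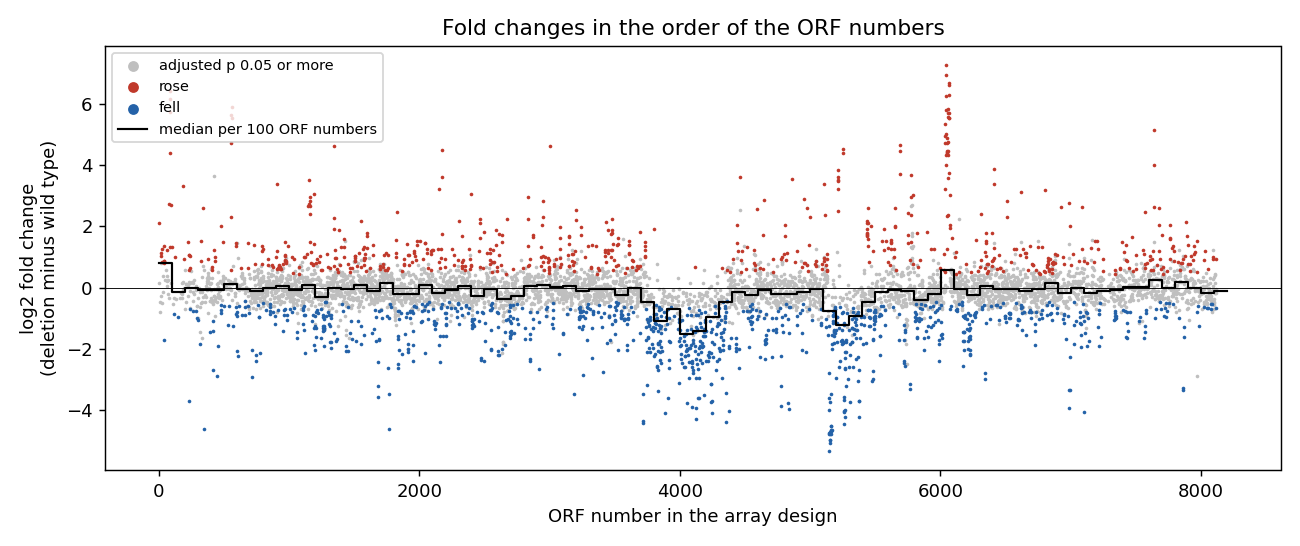
Log2 fold change (deletion minus wild type, vertical axis) of each tested numbered ORF against its ORF number (horizontal axis), with red points for ORFs that rose, blue points for ORFs that fell, grey points for the others and a black line for the median per 100 ORF numbers. The red column lies at ORFs 6036 to 6073, the deepest blue column at 5138 to 5172, and the black line drops over 3701 to 4400 and 5101 to 5500, to -1.53 at its lowest.

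Changes of the same direction lay next to each other far more than in shuffled order. There were 10 runs of 10 or more neighbouring ORFs that changed the same way by 2-fold or more, of which 8 fell and 2 rose, and they spanned 159 changed ORFs. The longest run in any of 1000 shuffles had 9 ORFs. Besides the longest run in each direction, ORFs 5256 to 5270 fell (median log2 fold change -2.66, 15 of 15 tested) and ORFs 5434 to 5444 rose (1.77, 11 of 11). Runs that fell also lay at ORFs 1263 to 1272 (-1.33), 3992 to 4019 (-1.39), 4032 to 4055 (-1.95), 4138 to 4158 (-1.92), 4237 to 4254 (-2.13) and 6219 to 6230 (-1.60). The number of runs was 2 with normexp and 6 with the authors' table.

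In the stretch that fell, the median level of its 32 tested ORFs was -1.55 ± 0.54 (log2, SD, n = 3) on the deletion arrays and 2.69 ± 0.06 (n = 3) on the wild-type arrays. Each deletion array lay below each wild-type array, and the 2-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. The ORFs had been picked by their fall on these same arrays, so this separation followed from the choice and is no independent test. All 32 ORFs were well above background on every wild-type array, and 27, 32 and 26 of them were on deletion replicates 1, 2 and 3. The fall from the wild-type mean was deeper on deletion replicate 1 (-5.26) than on replicates 2 (-4.20) and 3 (-4.11). The median log2 fold change of this stretch was -4.59, and -3.13 with normexp. In the stretch that rose, the median level was 1.11 ± 0.29 (n = 3) on the deletion arrays and -3.67 ± 0.36 (n = 3) on the wild-type arrays, with an exact permutation p of 0.1. The same limit on this p holds for the stretch that rose. Of its 38 ORFs, 12 were not well above background on any wild-type array. With these at their bounds the median log2 fold change was 4.42. It was 2.15 with normexp and 2.80 over the ORFs well above background on all 6 arrays.

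**Figure D2:**
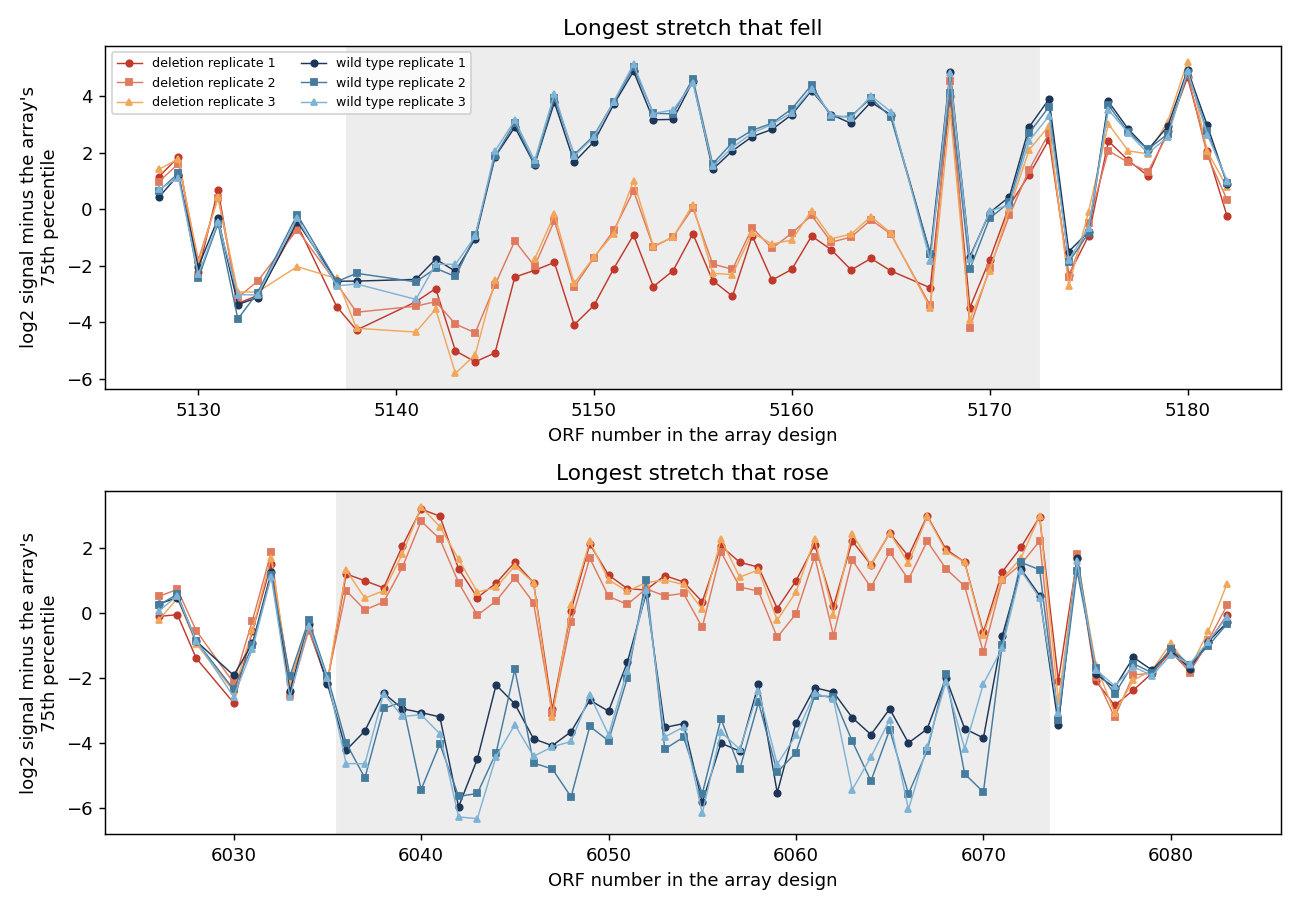
Level of each ORF on each of the 6 arrays (log2 signal minus the array's 75th percentile, vertical axis) against ORF number (horizontal axis), for the stretch that fell (top) and the stretch that rose (bottom), each shaded and with 10 ORF numbers on either side. Deletion arrays are in red and orange and wild-type arrays in blue; within the shading the median levels are -1.55 against 2.69 at the top and 1.11 against -3.67 at the bottom.

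Outside the stretch from 5138 to 5172, the regions 3701 to 4400 and 5101 to 5500 held 676 tested ORFs, of which 334 fell and 41 rose. Their median log2 fold change was -0.78, against -0.07 for the 5272 other tested ORFs with a number, of which 641 rose and 689 fell. The shift was -0.75, -0.66 and -0.97 on deletion replicates 1, 2 and 3 relative to the wild-type mean. Each bin of 100 ORF numbers in these regions passed the shuffle test at an adjusted p under 0.05, by which the regions had been defined. Over all 82 bins, 13 passed as lower and 11 as higher. For the bin of ORFs 4001 to 4100, the lowest (median -1.53, 37 of 57 tested ORFs fell and 0 rose), the Benjamini-Hochberg adjusted shuffle permutation p was 0.00126, the smallest the shuffles gave over 82 bins. Bins outside these regions reached this value too, such as ORFs 5801 to 5900. The shuffle treats ORFs as independent, so its p-values tend to be too small: log2 fold changes of adjacent ORFs correlated at r = 0.476 even outside these regions and the longest run in each direction. The regions' median was -0.47 with normexp.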

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

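The tests of contig features, of the risen stretch and of the spread between deletion arrays in this part were chosen only after the result was seen. Besides numbered ORFs, the arrays carried 36 features named as contigs, with 2 probes each, that enter no comparison above. Of these, 2 stood at least 2-fold higher in the deletion strain than in the wild type. Contig4_forward rose by 3.01 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0129 over the 36 features), from -2.01 ± 0.48 (SD, n = 3) in the wild type, and its SD in the deletion strain was 1.32 (n = 3). Contig4_reverse rose by 2.39 (limma adjusted p = 0.0340), from -3.48 ± 0.66 to -1.09 ± 1.31 (SD, n = 3 each). All 12 measurements of Contig4_forward (2 probes on 6 arrays) were well above background, against 8 of 12 for Contig4_reverse, so the size of its rise is less certain. No explanation was tested for either, and the meaning of the feature names was not used here.

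Of the 38 ORFs from 6036 to 6073, 36 rose; the median log2 fold change was 4.73, or 4.42 with bounds, 2.80 over ORFs well above background on all arrays and 2.15 with normexp. A fault of 1 array or of the second slide is argued against because the longest risen run, found with each of the 6 arrays left out in turn, was again 6036 to 6073, and its median on the array left out lay at least 4.07 (log2) from the nearest array of the other strain. The same gain of DNA copies for every ORF of the stretch was weighed on the 12 ORFs well above background on all 6 arrays. Their log2 fold changes ran from 0.02 to 4.72, with an interquartile range of 1.80, or 9.02 times the median standard error. This cannot decide the question, because the standard error leaves out ordinary differences between ORFs. Bright ORFs outside the broad regions, not matched to this stretch, had a median interquartile range of 0.70. The 12 ORFs were also kept by their wild-type signal. A rise in transcription and a gain of DNA copies in the deletion strain both remain candidate explanations, as hypotheses found and tested on the same data. Whether whiGch acts on this stretch, or LG01 differs from L10 there in another way, was not tested.

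Deletion arrays lay farther apart than wild-type arrays. The second slide alone does not account for this, because deletion replicates 1 and 2, on the same slide, differed by a root mean square of 0.666 (log2), whereas the array on the second slide differed from them by 0.729 and 0.503; a part from the slide stays open. Low signal in itself is argued against as well, because the largest difference between wild-type arrays was only 0.377. Their 75th percentiles of 115 to 141 were close to that of the dimmest deletion array, 124. Unequal signal cannot be judged this way, because the wild-type arrays were alike in signal. The deletion arrays stood at 124, 210 and 235, and the brighter ones, replicates 2 and 3, were the closest pair (0.503). A part from unequal signal therefore stays open. A difference between cultures or growth states of the deletion samples may remain, and was not tested.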

How the results depend on the processing

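Every alternative for the runs, the stretches and the broad regions, and the 75th percentile over genes, was chosen only after the result was seen; the other alternatives were planned. The named genes, the stretches and the broad regions kept their direction in all alternatives run for them, but the balance of rises and falls turned with median centring (970 and 931) and the authors' table (966 and 961). The count of 1849 changed genes was 1078 with a minimum log2 change of 1, 967 at an adjusted p under 0.01 and 663 with treat, which are stricter by construction; it ranged from 1093 to 2529 (without wild-type replicate 3 and without deletion replicate 1) when 1 array was left out, was 1162 without wild-type replicate 2, and stayed within 1.5 times in the other settings. Arrays that share a title code showed no common deviation (correlations of deviations -0.14 and -0.0016 for the 2 shared codes). So few pairs cannot exclude a pairing, and the labels do not say what the codes mark. A replicate block on these codes gave 1510 genes. With normexp there were 2 runs, and the medians were -3.13 for the stretch that fell, 2.15 for the stretch that rose and -0.47 for the broad regions. An offset of 50 compresses dim signals, but this setting also changed the background correction and the signal used. Their parts were not tested separately. There were 6 runs with the authors' table, without a filter, with a filter on all 6 arrays and with the unmoderated test, and with that filter on all arrays the stretch that rose had a median of 2.80. The broad regions had medians of -0.67 with quantile normalisation and with median centring, and -0.58 with the authors' table. In these 3 settings the median over all tested genes moved the same way, from -0.12 to -0.049, -0.0046 and -0.015. Median centring only subtracts a constant from each array, so with it the move of the regions came from the scaling of all genes. With quantile normalisation and the authors' table, a part of the move came from that scaling. The regions' median was -0.54 with the filter on all arrays, which kept 463 of the 676 ORFs and left out those that were dim on any array. It was -0.66 with slide as a block, which equals leaving out deletion replicate 3. The shift was deepest on that array (-0.97, against -0.75 and -0.66 on deletion replicates 1 and 2). Leaving out 1 array gave -4.78 to -4.17 for the stretch that fell and -0.85 to -0.66 for the broad regions. The 4 named genes passed the test in all 16 or 17 alternatives run for each, with adjusted p of at most 0.0248. Scan date, single probes and the planned gene-list tests were not run. Signal over background limits the dimmest genes: 1577 were not tested.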

Other observations

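The split of the arrays was planned, and all other tests of this part were chosen only after the result was seen. Some transcripts were well above background in 1 strain only. There were 25 genes well above background on all 3 wild-type arrays and on no deletion array, and 24 of them lay in the regions of ORFs 3701 to 4400 and 5101 to 5500. These regions held 696 and 398 of the 7401 numbered ORFs. They had been defined by lower levels on these arrays, so the overlap was in part set by that definition. All 25 passed the test, and their bounds had a median of at least 2.83-fold and reached 8.19-fold. In the other direction there were 42 genes, of which 37 passed the test and 12 lay in the stretch from 6036 to 6073. Their bounds had a median of at least 2.37-fold and reached 37.0-fold. Both sets were picked by detection on the arrays that the test compares, so passing it is no independent support.

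Fold changes of neighbouring ORFs resembled each other outside the broad regions and the longest run in each direction too. Across genes, which are not independent replicates, the log2 fold changes of ORFs with adjacent numbers correlated at r = 0.646 (Spearman's rho 0.481, 4829 pairs). The correlation was r = 0.476 after leaving out the broad regions and the longest run in each direction. Shorter runs outside the regions, such as ORFs 1263 to 1272, stayed in. At a distance of 10 numbers r was 0.271 over all pairs and 0.0320 after leaving these out, and the largest r in shuffled order at that distance was 0.0495. At the low end of the numbering, 18 of the 36 tested ORFs from 1 to 100 rose and 1 fell, with a median log2 fold change of 0.80. Genes listed by probe ID only went both ways, with 59 rises and 56 falls among 544 tested. Of the 36 contig features, 3 rose and 5 fell, 6 of these 8 by 2-fold or more. The 2 probes differed in sign for 6 of the 36 features. Contig10_reverse, among the 5 that fell, was one of them, with log2 fold changes of -1.54 and 0.04. Contig14_forward fell by 1.06 and Contig14_reverse by 1.07 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00157 and 0.00105), and Contig6_forward fell by 3.51 and Contig6_reverse by 3.86 (limma adjusted p = 8.62e-05 for both).

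In the regions from 3701 to 4400 and 5101 to 5500, without the stretch from 5138 to 5172, the median log2 fold change was -0.78. A stronger shift of dim probes is argued against by ORFs outside the regions matched on mean level, whose median over 1000 draws was never below -0.149. Loss of the DNA of all ORFs there is argued against because 71.0% of the tested ORFs were well above background on all 3 deletion arrays. Shares per array were also taken over tested and untested ORFs, here with the stretch from 5138 to 5172 included. On deletion replicates 1, 2 and 3 they were 53.3, 74.3 and 43.7% in the first region and 69.3, 85.7 and 59.8% in the second. The wild-type arrays gave 60.6 to 75% and 70.6 to 82.4%. ORFs elsewhere gave 86.2, 95.3 and 81.3% on the deletion arrays and 79.4 to 88.7% on the wild-type arrays. ORFs of the regions were thus less often well above background in both strains. Loss of a part stays open. The same fold loss for every ORF is argued against by the 246 ORFs with a wild-type level above -1: their interquartile range was at least 1.70 times that of ORFs matched on wild-type level. Lower transcription of many, but not all, ORFs of these regions in the deletion strain may be the explanation, and whether it follows from whiGch or from another difference between the strains was not tested.

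The 6 arrays can be divided into 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 1849 changed genes (limma), 1 of the 10 reached that count, and the highest count of the other divisions was 0. Every other division mixed the strains within each group, which put the strain difference into the spread between arrays. This lowers their counts, so the 0 is no measure of false calls.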
